A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

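RNA of budding yeast grown with cryptolepine was compared with RNA of untreated yeast on 8 spotted DNA arrays, each carrying a treated and an untreated preparation in different dyes. Per the labels, cultures grew for 15 h at 30 °C in rich YPD medium with or without the compound, and 15 µg of total RNA was labelled indirectly with Cy3 or Cy5. Cryptolepine is an indoloquinoline alkaloid that binds DNA and has antimalarial and cytotoxic activity. It was given at 7.5 µM (preparations A and B) or 17 µM (preparations C and D), which the labels equate with 20% and 40% inhibition. Each treated preparation was set against the untreated preparation of its own letter on 2 arrays with the dyes swapped. The 4 letters are therefore the replicates, 2 per dose. The labels call each dose a duplicate but do not say in so many words that the letters were separate cultures. The file headers carry preparation numbers that A shares with C and B with D, and what these stand for is not given. The tests treat the 4 letters as independent, so p-values of single genes measure the spread between these preparations.

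Per the file headers, slides were scanned with a GenePix 4000B and read with GenePix Pro 5.0.1.33. The scanner tables hold spot and local background intensity at 635 nm (Cy5) and 532 nm (Cy3) as median pixel intensity, without normalization, per the file headers. They also hold the percent of each spot's pixels brighter than background plus 2 SD, again per the file headers. The deposited series table holds log2 ratios of treated over untreated background-subtracted medians, turned so that treated is on top in both dye orientations and not centred. This was checked by recomputing the ratios: in 7 columns 92.2% to 94.1% of genes lay within 0.001 of the value from the scan. The scanner table of array C with treated RNA in Cy5 was byte for byte that of array D in the same orientation. Of 3045 genes, 2807 lay within 0.001 of the column for D (r = 0.991), against r = 0.569 with the column for C. That array therefore entered as its deposited log2 ratios, centred on their median. Its scale, centring and direction could not be set against a scan of its own. The SD of its log2 ratios was 1.48, against 0.45 to 0.65 on the other 7 arrays. Those 7 were background-corrected, normalized and filtered as described next, while this array was only centred, so the SDs are not like for like. Steps upstream of these tables other than those named here are not given in the sources used here.

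Intensities of the other 7 arrays were background-corrected with normexp (offset 50) and normalized by loess within each array (span 0.3) in limma 3.58.1 under R 4.3.3. The offset draws ratios of dim spots on these 7 arrays towards 0. Array C in the Cy5 orientation entered without this correction, and the spot filter also moved sizes of dim genes. Means of dim genes are therefore not lower bounds. Spots were used if, in at least 1 channel, signal was at least 2 times background and 75% of pixels exceeded background plus 2 SD, the rule the labels state. For array A with treated RNA in Cy5 only the pixel criterion could be applied. This filter and the deposited table kept or dropped the same genes for 71.3% to 87.3% of genes per array. Spots of one gene were averaged, and the 2 arrays of a letter were averaged into 1 value. Fewer than 3000 genes (887) had a value on all 8 arrays, so by the rule fixed in advance a gene was tested if every letter had a value on at least 1 array, which gave 2469 genes. Array C with treated RNA in Cy3 gave values for only 1275 genes. For many tested genes the value of C therefore came from its deposited ratios in the Cy5 orientation alone. Dye effects cancel in full only where both arrays of every letter gave a value, and 1582 of the 2469 lacked at least 1 array. In letter C they may not cancel even then, since its array in the Cy5 orientation was only centred. Gene names came from the RefSeq table for R64, which matched 5662 of 6212 identifiers. The other 550 kept their systematic names.

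Limma fitted 1 coefficient per dose to the 4 values of each gene with empirical Bayes moderation and Benjamini-Hochberg adjustment, and a gene was called at adjusted p under 0.05. The tests were the mean of both doses against 0, each dose against 0 with the spread shared between doses, and 17 µM minus 7.5 µM. A call at both doses means the first of these tests and does not ask for a call at each dose. There were 30 gene lists. A list with at least 5 measured members was tested with camera (preset inter-gene correlation 0.01), with camera at an estimated correlation and with fry beside it. Camera sets members against the other genes. With the preset correlation its p-values therefore rest on the spread over genes more than on that between preparations. At an estimated correlation it has the 2 residual degrees of freedom of the fit. It can then hardly call any of 29 lists, so a list it does not call is not shown to be unshifted. Named genes followed a rule: the 12 largest rises and 12 largest falls called at both doses with 1 sign in all 4 letters, up to 5 each way per dose, up to 10 for the difference (or the 5 with the smallest p where none passed), up to 4 members per list by smallest p, and TOP1, TOP2, RAD52, RNR3, HUG1, PDR5, SNQ2 and YOR1. Groups, tests, lists, this rule and most alternatives were chosen before the data were examined. The self-test on simulated data recovered 35% of changes of log2 1 and 91% of log2 2 among all tested genes, with 8 false calls in 2269 unchanged genes, 6 of them in genes missing from an array. Among the 887 complete genes it recovered 98% and 100%, with 8 false calls in 687. The simulation drew 4 independent letters and added a fixed dye effect, with no other difference between the 2 arrays of a letter. Its false calls therefore do not cover deviations shared between letters.

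Alternatives covered background correction, normalization, the spot filter, completeness, a dye term in a fit of all 8 arrays, each orientation alone, the deposited ratios, an intensity trend with robust moderation, own-dose pairs only, each letter left out and a size minimum. Chosen after seeing the data were 3 treatments of array C in the Cy5 orientation (left out, loess, rescaled), complete genes with each letter left out, and a replicate block. Arrays with treated RNA in Cy3 were scanned on another day than those with treated RNA in Cy5 whose scan is known, so orientation and scan day cannot be separated, and a planned scan-day block would equal the dye term and was not run apart. The number of arrays limits the precision.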

Results

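Transcript levels of Saccharomyces cerevisiae grown with cryptolepine were measured against untreated yeast on 8 arrays, 4 at 7.5 µM and 4 at 17 µM. Each dose had 2 preparations (A and B, then C and D), and every preparation was hybridized in both dye orientations. The arrays carried 7200 spots, of which 6542 held genes. Usable gene spots ranged from 1347 on array C with treated RNA in Cy3 to 3489 on array A with treated RNA in Cy5, and of 586 empty spots 1 to 4 passed the same rule. Median brightness over background was low, 11 to 55 units per channel and array. Correlations across genes, which are not independent replicates, averaged r = 0.76 between arrays of one orientation (0.55 to 0.88, 12 pairs of arrays). They averaged r = 0.34 between the 2 arrays of one preparation (0.17 to 0.57). Medians per orientation are therefore given for each tested gene list. In what follows, values are log2 of treated over untreated with the SD over the 4 preparations (n = 4), unless stated otherwise. Single genes were tested with limma and gene lists with camera.

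The first question was which transcripts differed between treated and untreated yeast over both doses. The largest rises were in stress proteins. HSP12 (YFL014W, chromosome VI), a small membrane-protecting heat shock protein, rose by 3.10 ± 0.88 (adjusted p = 0.0259), and HSP30 (YCR021C, chromosome III), a stress-induced plasma membrane protein, rose by 3.08 ± 0.15 (8.44-fold, adjusted p = 0.0170). SPI1 (YER150W, chromosome V), a cell wall protein of the stress response, rose by 3.06 ± 0.27 (8.32-fold, adjusted p = 0.0170). The largest fall was in FIT3 (YOR383C, chromosome XV), a cell wall mannoprotein that retains iron-siderophores, at -2.47 ± 0.17 (adjusted p = 0.0173). PHO5 (YBR093C, chromosome II), the repressible secreted acid phosphatase, followed at -1.94 ± 0.25 (adjusted p = 0.0233).

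Among the other large rises were HSP26, a small chaperone (2.58 ± 0.97), BTN2, a protein-sorting factor of the stress response (2.28 ± 0.46), and TPO2, a polyamine exporter (2.04 ± 0.58). ROQ1 (1.98 ± 0.23), RTC3 (1.97 ± 0.24), HOR7 (1.94 ± 0.34) and MSC1 (1.92 ± 0.23) also rose. The reading frames YOL150C (2.70 ± 0.46, and 1.29 without the spot filter) and YFL015C (2.19 ± 0.18) completed this group. Other large falls were in ARN2, a siderophore transporter (-1.85 ± 0.30), TIR1, a cell wall mannoprotein (-1.81 ± 0.28), PHO12 (-1.76 ± 0.23), ABP140 (-1.66 ± 0.56), PHO11 (-1.62 ± 0.35), FIT2 (-1.47 ± 0.19) and AVO2, a subunit of the TORC2 kinase complex (-1.46 ± 0.21). The frames YMR290W-a (-1.82 ± 0.25), YNL143C (-1.80 ± 0.62) and YHR095W (-1.61 ± 0.38) were measured only with treated RNA in Cy3, so a dye effect cannot cancel in them. The untreated channel was well above background on only 1 of 7 scanned arrays for YFL015C and ROQ1, 2 for HSP12 and BTN2 and 3 for TPO2 and MSC1, and the treated channel on 2 for ARN2 and 3 for FIT3, ABP140, YMR290W-a, YNL143C and YHR095W, so the sizes of these changes depend on the background correction. With plain subtraction ROQ1 was at 3.14. Of these 24 genes, BTN2 differed most between orientations among the rises, 1.16 with treated RNA in Cy5 and 2.95 with it in Cy3. Calls ended without background subtraction for ABP140 (-1.76, adjusted p = 0.0608), without the spot filter for YNL143C (-1.27, adjusted p = 0.118) and YHR095W (-0.95, adjusted p = 0.0828), and with plain subtraction for YMR290W-a (-2.93, adjusted p = 0.0521; -1.18 without the spot filter). Every single-gene call in this comparison ended without preparation A, without preparation B and with a replicate block from the file headers, where limma called 0 genes. Among the complete genes, those with values on all 8 arrays, the 69 called genes that could be tested were all still called without A and without B.

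**Figure D1:**
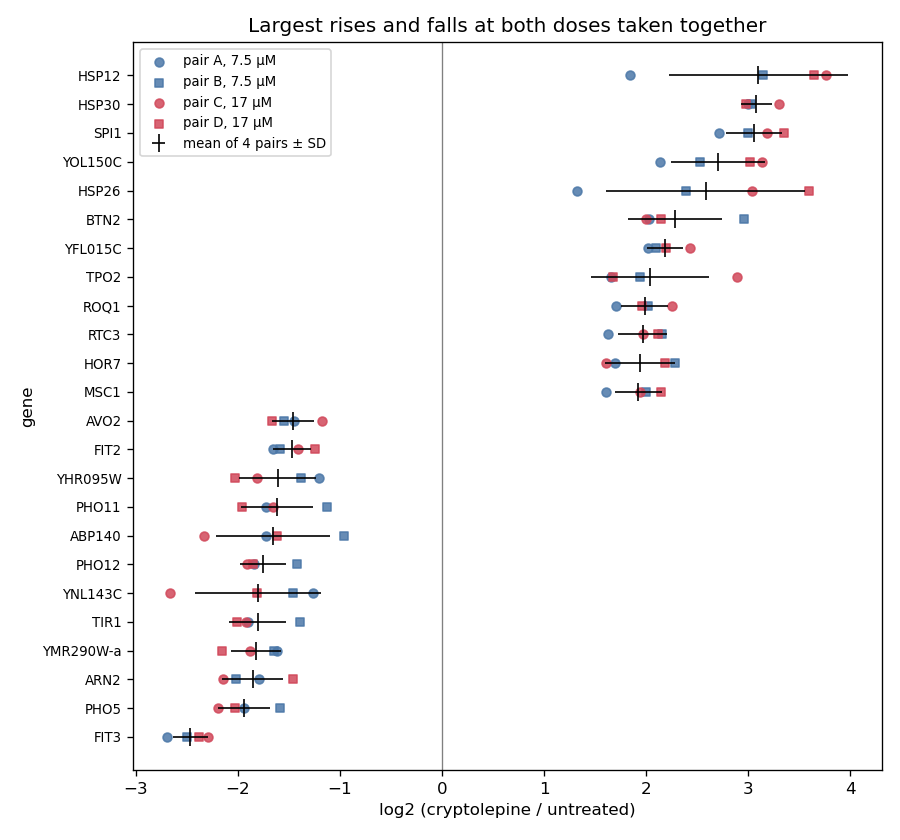
The 12 largest rises and 12 largest falls past adjusted p 0.05 for the mean of both doses, on a horizontal axis of log2 (cryptolepine / untreated). Each marker is 1 preparation (A and B at 7.5 µM, C and D at 17 µM), and the black bar is the mean of 4 with its SD. By the rule that chose these genes, all 4 preparations lie on one side of 0 for each. Means run from HSP12 at 3.10 ± 0.88 to FIT3 at -2.47 ± 0.17.

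Heat shock proteins and general stress genes rose as lists with the preset correlation between genes, not with an estimated one (adjusted p = 0.618 for both). With 2 residual degrees of freedom the test with an estimated correlation could hardly call any list, so it does not decide. Of 27 measured heat shock proteins and chaperones, 11 rose and 0 fell (15 rose and 1 fell adjusted over the list alone), with a list median of 0.75 (adjusted p = 2.61e-10). Among them were FES1, an exchange factor for Hsp70 (1.80 ± 0.27), and HSP104, the protein disaggregase (1.60 ± 0.14). The member that fell in the list alone was SSB2, a ribosome-associated Hsp70, at -0.36 ± 0.05, with -0.77 in the Cy5 orientation and 0.05 in the Cy3 orientation. Of 17 measured general stress genes, 9 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.14 (adjusted p = 3.39e-12). CYC7, the stress-induced isoform of cytochrome c, rose by 1.89 ± 0.08, YGP1, a secreted glycoprotein, by 1.56 ± 0.22, and SOL4, a phosphogluconolactonase, by 1.53 ± 0.07. With treated RNA in Cy5 and in Cy3 the medians were 0.65 and 0.99 for heat shock proteins and 1.05 and 0.96 for stress genes. Over 23 other settings with the preset correlation the stress median ran from 0.40 (without the spot filter, 31 members) to 1.29 (adjusted p 3.49e-14 to 1.81e-05), with 0.68 by print-tip loess. The heat shock median ran from 0.53 to 1.01 (adjusted p 1.94e-13 to 0.00779).

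Lists of energy storage, respiration and chromatin also rose with the preset correlation, not with an estimated one (adjusted p = 0.715 for trehalose and 0.618 for the other 2 lists), and fry did not call trehalose genes (adjusted p = 0.0581). Trehalose and glycogen genes had a median of 0.51 (adjusted p = 0.00122), with 1 of 11 past the threshold (5 adjusted over the list alone): TSL1, a subunit of trehalose synthase, at 0.83 ± 0.16. TPS1, which makes trehalose phosphate, was at 0.95 ± 0.29 and did not pass (adjusted p = 0.0674). Respiratory chain genes had a median of 0.33 (adjusted p = 0.00264), and 2 of 11 rose (2 adjusted over the list alone), QCR8 of the cytochrome bc1 complex (1.53 ± 0.14) and NDE1, a mitochondrial NADH dehydrogenase (1.38 ± 0.24). Core histone genes had a median of 0.44 (adjusted p = 0.00394) with 0 of 8 past the threshold in limma (3 adjusted over the list alone), and HHT1, histone H3, was at 0.79 ± 0.27 (adjusted p = 0.0729). With treated RNA in Cy5 and in Cy3 the medians were 0.25 and 0.72 for trehalose, 0.32 and 0.42 for respiratory and 0.05 and 0.91 for histone genes. The histone median was 0.14 in a fit of the Cy5 orientation alone (adjusted p = 0.423), where trehalose genes were also lost (0.23, adjusted p = 0.299). Respiratory genes were lost in the Cy3 orientation alone (0.66, adjusted p = 0.160), with both channels past the filter (0.23, adjusted p = 0.0923) and, like trehalose genes (0.75, adjusted p = 0.0595), without array C of the Cy5 orientation (0.60, adjusted p = 0.0642). Histones were also lost without preparation D (0.56, adjusted p = 0.0610). Over the settings with the preset correlation the median ran from 0.23 to 0.77 for trehalose (adjusted p from 2.85e-05), from 0.23 to 0.66 for respiratory (from 5.84e-08) and from 0.14 to 0.89 for histone genes (from 0.000509).

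Lists of iron uptake and phosphate scavenging fell with the preset correlation, not with an estimated one (adjusted p = 0.618 for iron and 0.754 for phosphate genes), and fry did not call phosphate genes (adjusted p = 0.0583). Of 15 measured iron regulon genes, 4 fell and 0 rose (7 fell and 1 rose adjusted over the list alone), with a median of -0.67 (adjusted p = 0.0214). Those that fell were FIT3, ARN2, FIT2 and SIT1, a ferrioxamine transporter (-1.22 ± 0.38, and -0.78 without the spot filter). The member that rose in the list alone was ISU1, an iron-sulfur cluster scaffold, at 0.74 ± 0.21. Of 17 measured phosphate regulon genes, 4 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.67 (adjusted p = 0.00849). The 4 were the acid phosphatases PHO5, PHO12, PHO11 and PHO3 (-1.10 ± 0.19), which are close in sequence and can share signal on spotted probes. PHM8, a phosphatase induced at low phosphate, rose by 1.18 ± 0.31, and PHO84, the high-affinity phosphate transporter, was at -0.22 ± 0.26. PHM8, ISU1, SSB2 and PHO84 lie outside the naming rule and were chosen after their values were seen. Medians with treated RNA in Cy5 and Cy3 were -0.79 and -0.37 for iron genes and -1.09 and -0.14 for phosphate genes. The iron list was lost with both channels past the filter (-0.29, adjusted p = 0.187), and at larger medians in the Cy5 orientation alone (-0.998, adjusted p = 0.130) and without preparation D (-0.73, adjusted p = 0.133). The phosphate list was lost in the Cy3 orientation alone (-0.14, adjusted p = 0.208) and without array C of the Cy5 orientation (-0.16, adjusted p = 0.0642). Without preparation C the phosphate median was -0.24 (adjusted p = 0.00339), and with array C of the Cy5 orientation rescaled it was -0.36 (adjusted p = 0.00389). Without the spot filter, where 28 iron and 20 phosphate genes enter, the medians were -0.12 for iron (adjusted p = 0.00741) and -0.25 for phosphate genes (adjusted p = 0.00178). Over all these settings the smallest adjusted p was 0.000397 for iron and 0.00178 for phosphate genes.

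**Figure D2:**
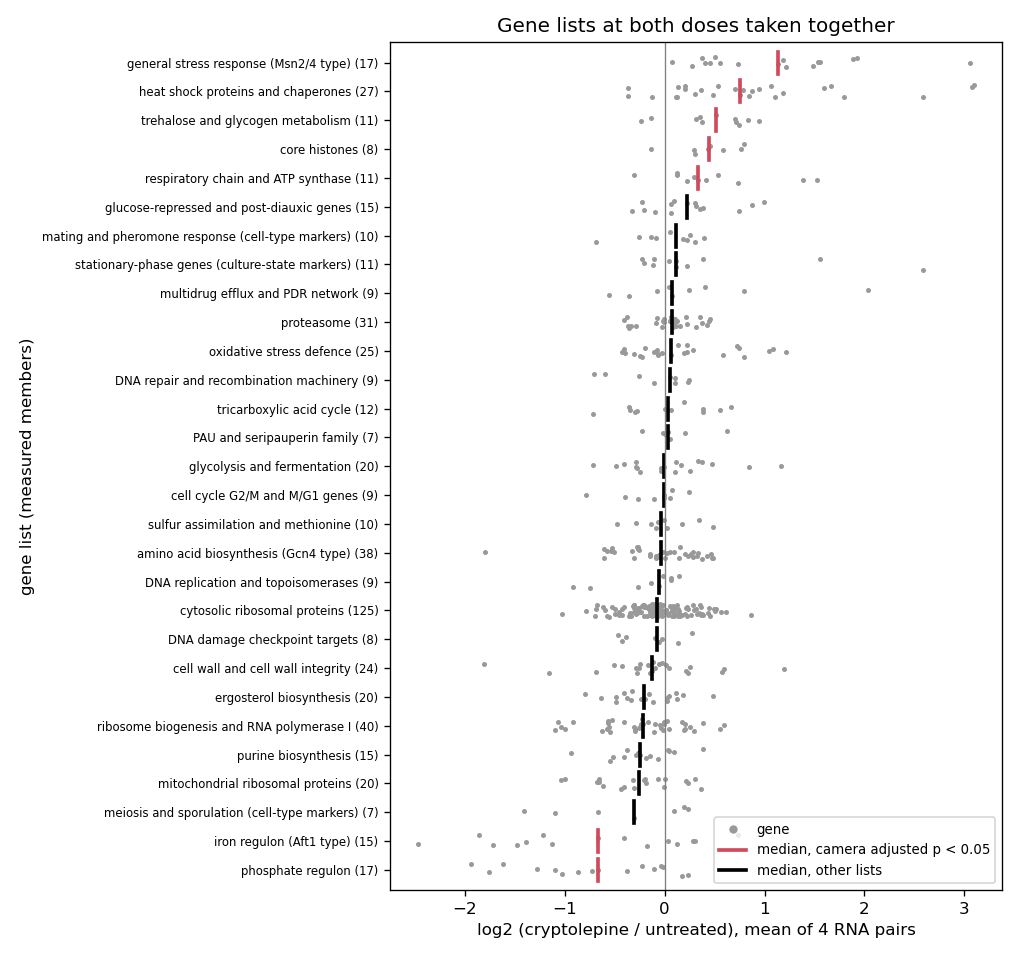
Gene lists for the mean of both doses. Each grey point is a measured gene at its log2 (cryptolepine / untreated), mean of 4 preparations, and each vertical bar is the list median, red where camera with the preset correlation gave adjusted p under 0.05. General stress genes have the highest median, 1.14, and the iron and phosphate lists lie at -0.67.

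No DNA damage signature passed the test, which covered 8 of the 20 checkpoint targets on the arrays. The 8 measured checkpoint targets had a median of -0.08 (adjusted p = 0.613) and 0 members past the threshold in limma (0 adjusted over the list alone). Camera did not call this list, while fry, which asks whether members move one way on balance, gave adjusted p = 0.00694, with 2 of 8 above 0. RNR4, a subunit of ribonucleotide reductase, was at -0.47 ± 0.22 (adjusted p = 0.195). TOP1, DNA topoisomerase I, was at -0.74 ± 0.79 (adjusted p = 0.272, 4 arrays). The efflux pump PDR5 was at -0.56 ± 0.44 (adjusted p = 0.222), with -0.13 in the Cy5 and -0.98 in the Cy3 orientation, and SNQ2, another efflux pump, was at -0.36 ± 0.21 (adjusted p = 0.253). Among genes on all 8 arrays PDR5 and RNR4 passed (adjusted p = 0.0306 and 0.0231). TOP2 (3 arrays), RAD52 (2), YOR1 (3), RNR3 (1) and HUG1 (1) had too few values for a test. Their values ran from -3.90 to -0.65 for TOP2, -0.13 to 0.36 for RAD52 and 0.002 to 0.40 for YOR1. Of the 7 scanned arrays TOP2 was well above background on 2 and RAD52 on 1, in the untreated channel only. TOP1 was so on 2 in the treated and 1 in the untreated channel. Hence 1 value of each of these 3 genes came from array C of the Cy5 orientation. That array entered without the offset, so its ratios of dim spots were not drawn towards 0. The lone values of the checkpoint targets RNR3 and HUG1 were 0.57 and 1.93, so their response is not settled. HUG1 was not well above background in either channel of the 7 scanned arrays. Its lone value therefore came from array C of the Cy5 orientation, whose scale could not be checked. Repair genes (9 of 33 measured, median 0.05, adjusted p = 0.854) and replication and topoisomerase genes (9 of 34, -0.06, adjusted p = 0.634) did not pass. Nor did efflux genes (9 of 25, 0.08, adjusted p = 0.432, TPO2 the 1 member that rose). With treated RNA in Cy5 and in Cy3 the medians were -0.14 and -0.01 for checkpoint targets, 0.20 and -0.20 for repair, 0.00 and -0.22 for replication and 0.16 and 0.05 for efflux genes.

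Ribosomal and biosynthetic genes did not pass as lists at both doses together among all tested genes. The 125 cytosolic ribosomal protein genes had a median of -0.08 (adjusted p = 0.613) that changed sign with orientation, -0.37 with treated RNA in Cy5 and 0.25 with it in Cy3. The 40 ribosome biogenesis genes were at -0.22 (adjusted p = 0.188; -0.54 and 0.19 per orientation), and RPL30 (-1.02 ± 0.30, adjusted p = 0.0507) and NOP12 (-1.07 ± 0.42, adjusted p = 0.0513) did not pass. Mitochondrial ribosomal proteins were at -0.25 (adjusted p = 0.511), amino acid genes at -0.04 (adjusted p = 0.854), sulfur genes at -0.03 (adjusted p = 0.873) and ergosterol genes at -0.20 (adjusted p = 0.108; ERG11 -0.80 ± 0.23). Purine genes had a median of -0.24 (adjusted p = 0.145), and ADE6 fell (-0.94 ± 0.16). Glycolytic genes were at -0.01 (adjusted p = 0.601), where GLK1, glucokinase, rose by 1.17 ± 0.12 and GPM1, phosphoglycerate mutase, by 0.84 ± 0.06. Oxidative stress genes were at 0.06 (adjusted p = 0.145), where the peroxidases PRX1 (1.09 ± 0.26) and CCP1 (1.04 ± 0.17) rose. Glucose-repressed genes were at 0.23 (adjusted p = 0.0718), tricarboxylic acid cycle genes at 0.03 (adjusted p = 0.634) and proteasome genes at 0.08 (adjusted p = 0.294). Cell wall genes were at -0.12 (adjusted p = 0.601), with TIR1 and TIR2 (-1.16 ± 0.36) lower and TIP1 higher (1.20 ± 0.29). Markers of culture and cell state did not pass either. Stationary-phase genes were at 0.11 (adjusted p = 0.112) and mating genes at 0.12 (adjusted p = 0.636). Meiosis genes were at -0.30 (adjusted p = 0.601), where SPS4 fell (-1.41 ± 0.49). G2/M genes were at -0.01 (adjusted p = 0.634) and PAU genes at 0.03 (adjusted p = 0.601). Medians with treated RNA in Cy5 and in Cy3 had opposite signs for amino acid (-0.24 and 0.10), sulfur (0.04 and -0.12), purine (-0.31 and 0.13), glycolytic (-0.04 and 0.02), tricarboxylic acid cycle (-0.18 and 0.17), proteasome (-0.08 and 0.32), cell wall (0.09 and -0.37), stationary-phase (0.36 and -0.07) and PAU genes (0.26 and -0.17). They had 1 sign for mitochondrial ribosomal (-0.30 and -0.11), ergosterol (-0.24 and -0.14), oxidative stress (0.01 and 0.06), glucose-repressed (0.24 and 0.23), mating (0.11 and 0.10), meiosis (-0.43 and -0.17) and G2/M genes (-0.11 and -0.05). The G1/S list had 4 measured members and was not tested. Adjusted over the list alone, 7 of 25 oxidative stress, 2 of 12 tricarboxylic acid cycle, 1 of 15 glucose-repressed and 2 of 20 glycolytic genes rose, as did 2 of 11 stationary-phase genes (YGP1 and HSP26, called over all genes too) and 1 efflux gene. In cell wall genes 2 rose and 2 fell, 1 purine and 1 meiosis gene fell, and the other lists of this paragraph had 0. Among complete genes 4 of these lists passed, ribosomal proteins, purine, ergosterol and stationary-phase genes, each at adjusted p = 0.0442. There 11 of 89 ribosomal protein genes rose and 15 fell. Without background subtraction the calls of ADE6 (-0.96, adjusted p = 0.0567), PRX1 (1.08, adjusted p = 0.0606), TSL1 (0.89, adjusted p = 0.0545) and TIR2 (-1.24, adjusted p = 0.0608) ended at about the same sizes. GPM1 was lost by median centring (0.73, adjusted p = 0.0576) and print-tip loess (0.83, adjusted p = 0.0544), TIR2 also by print-tip loess (-1.10, adjusted p = 0.0682) and in the Cy5 orientation alone (adjusted p = 0.0576), TIP1 in the Cy3 orientation alone (0.37, adjusted p = 0.0866) and SPS4 without the spot filter (-0.93, adjusted p = 0.0567).

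Altogether 106 of 2469 genes passed for the mean of both doses, 64 up and 42 down, while 0 passed at 7.5 µM and 0 at 17 µM. Of the 106, 89 changed by at least 1 on the log2 scale, and all 106 had 1 sign in the 4 preparations. A call asks for a mean large against its spread, which favours 1 sign. The balance of rises and falls depended on the setting, with 137 up and 137 down among complete genes, 156 and 157 with a dye term, 147 and 157 with array C of the Cy5 orientation rescaled and 300 and 620 without preparation D. In 102 of the 103 measured in both orientations the orientation means shared a sign, which selection by the mean of both also favours. Of 69 called genes with values on all 8 arrays, all 69 were also among the 274 of 887 called in a fit of complete genes. The other called genes lacked at least 1 array, so dye effects may not cancel in full in them. In preparation C they need not cancel in complete genes either, since its 2 arrays were processed differently. The SD of log2 ratios was 1.48 on its array with treated RNA in Cy5 and 0.55 on that with it in Cy3. The count rested on which preparations entered: 0 without A, 0 without B, 153 without C and 920 without D, each of which leaves 1 dose with a lone preparation assumed to vary like the rest. It also moved over 1.5 times to 0 with a replicate block from the file headers, whose preparation numbers pair A with C and B with D across the doses, and to between 207 and 446 under 12 other settings, among them 277 without array C of the Cy5 orientation and 304 with that array rescaled. The deviation of A from B correlated with that of C from D at r = 0.490 over 887 genes, while these p-values treat the 4 preparations as independent. Without array C of the Cy5 orientation 89 of the 106 called genes could still be tested, and 87 of these were called. SIT1 missed the threshold when that array was fitted by loess (-1.16, adjusted p = 0.0544).

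**Figure D3:**
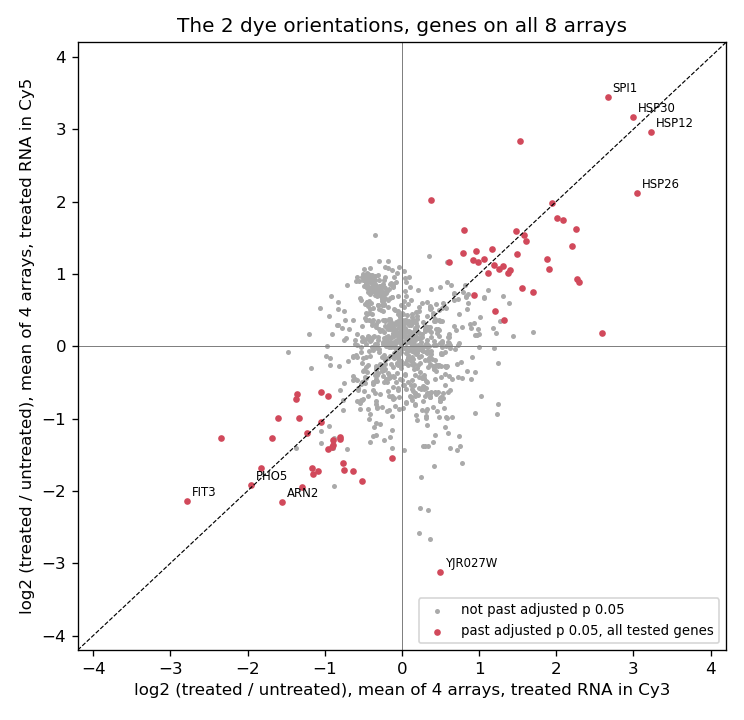
The 2 dye orientations compared over the 887 genes on all 8 arrays, each point a gene at its mean log2 (treated / untreated) over 4 arrays with treated RNA in Cy3 (horizontal) and in Cy5 (vertical). Red points passed adjusted p 0.05 for the mean of both doses. The correlation across genes was r = 0.31. Of 103 called genes measured in both orientations 102 had 1 sign in both, and the 69 on all 8 arrays are shown. A call asks for a mean large against its spread, which favours a shared sign.

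At 7.5 µM, the concentration set at 20% inhibition, the smallest p-values were in these genes (n = 2). HSP30 was at 3.01 ± 0.02 and SPI1 at 2.85 ± 0.20, and FIT3 was at -2.60 ± 0.14 (adjusted p = 0.0661 for each). YOL150C was at 2.33 ± 0.27 and YFL015C at 2.06 ± 0.06 (adjusted p = 0.102 for both). With an estimated correlation none of the 7 lists given next passed (adjusted p = 0.559 for stress, 0.615 for trehalose, 0.738 for phosphate and 0.488 for the other lists), and fry called 5. With the preset one general stress genes rose as a list (median 1.01, adjusted p = 1.10e-13, 9 of 17 up adjusted over the list alone), as did heat shock proteins (0.55, adjusted p = 3.17e-09, 11 of 27 up) and trehalose genes (0.53, adjusted p = 0.000187, 3 of 11 up). Core histones (0.71, adjusted p = 0.000146, 3 of 8 up) and respiratory genes (0.41, adjusted p = 0.000889, 2 of 11 up) also rose. Iron (-0.49, adjusted p = 0.000868, 4 down) and phosphate genes (-0.26, adjusted p = 0.0112, 4 down, 1 up) fell as lists. No single gene passed in limma (0 of 2469, 269 at an unadjusted p under 0.05), against 128 of 887 complete genes (67 up, 61 down), 57 with only the 2 preparations of this dose, without C or without D, 208 in the Cy3 orientation alone and 0 to 169 under other settings. In the Cy5 and in the Cy3 orientation alone the medians were 0.91 and 1.09 for stress, 0.30 and 0.95 for heat shock, 0.14 and 0.87 for trehalose, 0.31 and 1.10 for histone, -0.66 and -0.59 for iron and -1.03 and -0.20 for phosphate genes, and 0.78 in Cy3 for respiratory genes. In Cy5 alone trehalose genes were lost (adjusted p = 0.268), as were histones (0.0741) and, at a larger median, iron genes (0.0879). Iron was lost with both channels past the filter (-0.26, adjusted p = 0.110). Respiratory genes were at 0.23 with both channels past the filter (adjusted p = 0.0408), and were lost in Cy3 alone at a larger median (adjusted p = 0.0695). Without the spot filter the medians were 0.42 for stress, 0.26 for trehalose and -0.21 for iron genes, and stress genes were at 0.54 by print-tip loess. Phosphate genes were lost in the Cy3 orientation alone (-0.20, adjusted p = 0.278), without preparation A (-0.07, adjusted p = 0.222; -0.44 without B) and without array C of the Cy5 orientation (adjusted p = 0.0937), and among complete genes without A (adjusted p = 0.0849).

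At 17 µM, set at 40% inhibition, SPI1 was at 3.26 ± 0.12, HSP30 at 3.14 ± 0.23 and YOL150C at 3.07 ± 0.08 (n = 2, adjusted p = 0.0552 for each). FIT3 was at -2.34 ± 0.07 and YFL015C at 2.31 ± 0.17 (adjusted p = 0.0661 for both). With an estimated correlation none of the 7 lists given next passed (adjusted p = 0.671 for each), and fry called 0. With the preset one general stress genes rose as a list (median 1.27, adjusted p = 7.92e-11, 13 of 17 up adjusted over the list alone), as did heat shock proteins (0.86, adjusted p = 1.81e-10, 15 of 27 up) and trehalose genes (0.55, adjusted p = 0.0111, 1 of 11 up). Respiratory (0.32, adjusted p = 0.0194, 2 of 11 up), glucose-repressed (0.45, adjusted p = 0.0260, 0 of 15 up) and stationary-phase genes (0.45, adjusted p = 0.0343, 2 of 11 up) also rose. Over 17 other settings with the preset correlation the respiratory median ran from 0.15 to 0.57. Phosphate genes fell as a list (-1.03, adjusted p = 0.0111, 6 down, 1 up), while iron genes (-0.60, adjusted p = 0.0673) and histones (0.42, adjusted p = 0.112) did not pass. Among complete genes iron (-0.60, adjusted p = 0.00222, 6 of 11 down), ribosomal protein (-0.22, adjusted p = 0.000232) and ergosterol genes (-0.29, adjusted p = 0.0262) passed too. No single gene passed in limma (0 of 2469, 433 at an unadjusted p under 0.05), against 197 of 887 complete genes (98 up, 99 down), 893 without preparation D, 0 without A, B or C, 223 in the Cy5 and 172 in the Cy3 orientation alone, and 0 to 281 under other settings. Without D only 3 lists passed, and 4 were lost at larger medians: trehalose (0.62), respiratory (0.37) and phosphate genes (-1.25), each at adjusted p = 0.0608, and glucose-repressed genes (0.64, 0.0501). The size of the phosphate fall rested on preparation C: the median was -1.25 in C and -0.26 in D, and it was -0.26 without C (adjusted p = 0.00165), -0.20 without array C of the Cy5 orientation and -0.54 with that array rescaled. Without C the medians of stationary-phase and glucose-repressed genes were 0.01 (adjusted p = 0.375) and 0.17 (adjusted p = 0.141). Without array C of the Cy5 orientation respiratory (0.55, adjusted p = 0.229), trehalose (0.58, 0.0693), stationary-phase (0.33, 0.0942) and glucose-repressed genes (0.27, 0.218) were lost, with 5 to 9 members left, and stationary-phase genes also with it rescaled (0.19, 0.0584). Stationary-phase genes were at 0.93 without D. Without the spot filter the medians were 0.55 for stress, 0.26 for trehalose, 0.20 for respiratory and -0.25 for phosphate genes. In the Cy5 and in the Cy3 orientation alone the medians were 1.17 and 1.14 for stress, 0.70 and 1.14 for heat shock, 0.32 and 0.61 for trehalose, 0.27 and 0.29 for glucose-repressed, 0.65 and 0.16 for stationary-phase and -1.36 and -0.24 for phosphate genes, and 0.54 in Cy3 for respiratory genes. In the Cy3 orientation alone phosphate and trehalose genes (adjusted p = 0.0567 for both), respiratory (0.229), stationary-phase (0.122) and glucose-repressed genes (0.215) were lost, and in the Cy5 orientation alone trehalose (0.339) and glucose-repressed genes (0.183). With both channels past the filter respiratory (0.29, adjusted p = 0.154) and stationary-phase genes (0.45, 0.0686) were lost, without the filter stationary-phase (0.15) and glucose-repressed genes (0.05; adjusted p = 0.108 for both), and among complete genes glucose-repressed genes (0.29, adjusted p = 0.235), there also with each preparation left out (0.201 to 0.493).

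Whether the response differed between doses was tested directly, and 5 lists passed with the preset correlation and 0 with an estimated one (adjusted p = 0.703 for each) or by fry. Heat shock proteins were higher at 17 µM than at 7.5 µM (median difference 0.26, adjusted p = 4.59e-05, 24 of 27 genes above 0), and cytosolic ribosomal protein genes were lower (-0.21, adjusted p = 4.59e-05, 102 of 125 below 0). Stationary-phase (0.48, adjusted p = 0.0312), general stress (0.24, adjusted p = 0.0410) and glucose-repressed genes (0.24, adjusted p = 0.0410) were also higher at 17 µM. HSP26 was at 1.86 ± 0.75 at the lower dose and 3.31 ± 0.40 at the higher (n = 2 each, difference 1.46, adjusted p = 0.762). RPS1B (0.90 ± 0.49 and -1.05 ± 0.22), RPL34B, ECM33 and CNL1 had the smallest p otherwise, also at adjusted p = 0.762, and each lacked values on 2 to 4 arrays. Limma called 0 of 2469 genes (13 at an unadjusted p under 0.05) and 0 of 887 complete genes, with 405 without preparation D and 15 of the complete genes without it. With array C of the Cy5 orientation rescaled the general stress difference was -0.03 (adjusted p = 0.784) and heat shock proteins were at 0.13 (adjusted p = 0.0773). Without B the ribosomal protein difference was -0.12 (adjusted p = 0.00391), without array C of the Cy5 orientation -0.05 (adjusted p = 0.0254), and without A heat shock proteins were at 0.16 (adjusted p = 0.0280). In the Cy5 and in the Cy3 orientation alone the differences were 0.37 and 0.18 for heat shock and -0.31 and -0.10 for ribosomal proteins, 0.54 and 0.46 for stationary-phase, 0.33 and 0.04 for general stress and 0.28 and 0.11 for glucose-repressed genes. The stationary-phase difference was 0.26 without B, 0.18 without C and 0.85 without D, that of general stress genes 0.10 without A and 0.15 without D, and that of glucose-repressed genes 0.05 without A, 0.39 without B, 0.15 without C and 0.36 without D. By median centring the differences were 0.14 for heat shock and -0.33 for ribosomal proteins. The phosphate list did not differ past the threshold (median -0.32, adjusted p = 0.0743), except among complete genes (-0.29, adjusted p = 0.00812). Without preparation D only 1 list passed, and ribosomal proteins were at -0.20 (adjusted p = 0.372). Over 23 settings the call was lost in 1 for heat shock proteins, 1 for ribosomal proteins, 7 for stationary-phase, 14 for glucose-repressed and 16 for general stress genes. Those for stationary-phase genes were no filter, both channels past it, array C rescaled, preparation C or D left out, and complete genes without A or D (adjusted p 0.0600 to 0.360). Those for glucose-repressed genes were no filter, both channels past it, each orientation alone, preparation A, C or D left out, the 3 other treatments of array C, complete genes, and complete genes without A, C or D (adjusted p 0.0504 to 0.952). General stress genes were lost with array C rescaled, as given, and with no background subtraction, median centring, print-tip loess, no filter, both channels past it, complete genes, the Cy3 orientation alone, preparation A, C or D left out, array C left out or by loess, the replicate block, and complete genes without A or D (adjusted p 0.0504 to 0.999). Across genes the changes at 7.5 µM and at 17 µM correlated at r = 0.57 over all tested genes, 0.85 over complete genes and 0.97 over the 106 called genes. These 106 were selected for change in the mean of both doses.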

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

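The tests for channels taken the wrong way round, for dye effects on stress and heat shock genes and for slower growth were chosen only after the result was seen.

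Of 35 groups of 4 values examined, 5 held a value far from the other 3, where chance gives about 1 in 20. HSP30 was at 3.30 in preparation C against 2.98 to 3.03 in the others, and BTN2 at 2.96 in B against at most 2.14. TIR1 was at -1.39 in B against -2.01 to -1.90, and PHO12 at -1.42 in B against -1.91 to -1.84. The SD of log2 ratios on array C with treated RNA in Cy5 was 1.48 against 0.45 to 0.58 on the other arrays of that orientation. That array is the one entered as deposited ratios, since its scan matched that of array D. The other arrays were background-corrected with an offset, normalized by loess and filtered, so these SDs are not like for like. No explanation was tested for the 4 genes.

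A difference between the doses set 5 gene lists apart. Heat shock proteins (0.26), general stress genes (0.24), glucose-repressed genes (0.24) and stationary-phase genes (0.48) were higher at 17 µM, and cytosolic ribosomal proteins were lower (-0.21), each a median difference in log2 tested as such. Adjusted p was 0.703 for each list with an estimated correlation, and the general stress difference was -0.03 with array C of the Cy5 orientation rescaled.

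Arrays of one dye orientation resembled each other more than the 2 arrays of one preparation did (mean r = 0.76 against 0.34). Channels taken the wrong way round in one orientation would make stress genes rise in one and fall in the other, yet 82.4% of general stress genes (14 of 17) had 1 sign in both, which argues against it. Gene-specific dye effects predict that the orientation difference of a gene repeats between preparations. Over 887 genes the difference in A and B correlated with that in C and D at r = 0.899, so such effects may account for the pattern. Scanning days ran with orientation, so a dye effect and a scan batch cannot be told apart, and no biological explanation was tested.

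The falls of YMR290W-a, YNL143C and YHR095W were seen only with treated RNA in Cy3, and dye effects that cannot cancel could produce them. The bound written beforehand against this was met, since 100% of the genes at or under -1.5 in that orientation and measured in both (7 of 7) were also low in the other (median -1.68). That bound was set wrongly, because genes measured in both orientations leave out by construction those seen with 1 dye. The 3 frames themselves, without the spot filter, were at -0.08 ± 0.12, -0.10 ± 0.26 and 0.23 ± 0.36 in the Cy5 orientation, where their spots were dim. This reading was adopted after the result, so their falls and a dye effect cannot be told apart.

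Stress and heat shock genes rose together. Dye effects would leave one orientation near 0, but the lower of the 2 orientation medians over the 44 genes was 0.745 and the other 0.977. The wider scale of array C in the Cy5 orientation is also argued against, since the median without that array was 101% of that with it (0.863 against 0.857, 38 genes). Slower growth of the treated cultures, which the labels' 20% and 40% inhibition name, stays open: the 165 ribosomal protein and ribosome biogenesis genes were at 0.24 with treated RNA in Cy3 and at -0.37 with it in Cy5. A direct response to cryptolepine may lie behind the rise, but that and a response to slower growth cannot be told apart here.

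The 106 genes called for the mean of both doses were set against other sign splits of the 4 preparations. Of 8 splits 1, the real one, gave as many, and the highest of the others gave 0. With 8 splits the share cannot fall under 0.05.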

How the results depend on the processing

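Of these alternatives, 3 treatments of array C in the Cy5 orientation, complete genes with a preparation left out and the replicate block were chosen after seeing the data. General stress and heat shock genes kept direction and call in 23 settings with the preset correlation at both doses, at 7.5 µM and at 17 µM, but lost the call in each with an estimated one, and at 17 µM with fry. The test with an estimated correlation has 2 residual degrees of freedom and could hardly call any list, so these losses do not decide. Of 2649 values of named genes, 0 reversed, 141 lost and 442 gained the call and 20 changed direction with no call either way; of 2348 list values, 5 reversed, 85 lost and 108 gained it and 174 changed direction with no call. Counts of genes at both doses, 7.5 µM and 17 µM, against 106, 0 and 0, were 228, 9 and 46 with plain background subtraction, 207, 30 and 51 with no spot filter, 274, 128 and 197 for genes on all 8 arrays, 313, 72 and 116 with a dye term, 446, 0 and 223 with treated RNA in Cy5 alone, 414, 208 and 172 with it in Cy3 alone, 319, 32 and 83 from the deposited ratios, 219, 76 and 101 with an intensity trend, 277, 116 and 119 with array C left out, 304, 68 and 27 with it rescaled, 129, 4 and 37 with both channels past the filter, 127, 0 and 2 with median centring, 107, 0 and 3 with print-tip loess and 110, 0 and 3 with array C by loess. The replicate block gave 0, 0 and 0 and no background subtraction 86, 0 and 0. Own-dose pairs gave 57 at 7.5 µM and 0 at 17 µM, and a size minimum left 89 at both doses. Leaving out 1 preparation gave 0 to 920, 0 to 57, 0 to 893 and, for the dose difference, 0 to 405. In complete genes this gave 108, 30, 87 and 0 without A, 119, 0, 87 and 0 without B, 215, 169, 114 and 0 without C and 335, 169, 281 and 15 without D. A lone preparation was then assumed to vary like the others. Fewer genes tested, with no missing arrays, is part of the construction of the complete set. For the others the cause was not tested. Shifted lists, 7 at both doses, 7 at 7.5 µM, 7 at 17 µM and 5 for the difference, were 4 at both doses with array C left out and 0, 0, 0 and 0 with an estimated correlation. With fry they were 6, 5, 0 and 0; the 6 are 5 of the 7, without trehalose and phosphate genes, and checkpoint targets. For the difference they were 2 with no spot filter, 3 with both channels past the filter, 3 with array C rescaled and 3 in complete genes without A or D. At 7.5 µM complete genes without A gave 4. Leaving out 1 preparation gave 7 to 11 at 7.5 µM, 3 to 9 at 17 µM and 1 to 6 for the difference. Reversed were ribosomal proteins at 7.5 µM in Cy5 alone (-0.22) and at both doses in Cy3 alone (0.24), and, for the difference, general stress genes in Cy3 alone (0.0409, by the direction of the test) and with array C rescaled (-0.0326), and cell wall genes with array C left out (-0.14). The cause of these was not tested. Of the 106 called genes 83 were also called with no background subtraction, 105 with plain subtraction, 101 with no filter, 106 without C, 106 without D and 106 with array C rescaled. The replicate block pairs A with C and B with D, by preparation numbers in the file headers. Low signal over background, a median of 11 to 55 units, limited the genes that could be tested to 2469.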

Other observations

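Both tests in this part, on Ty elements and on pyrimidine synthesis, were chosen only after the result was seen, as were the genes named here.

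Several of the genes that fell were reading frames of Ty retrotransposons. As a hypothesis, transcripts of the whole class may have been lower with cryptolepine. Of 14 such frames on the arrays 12 were measured, all 12 were below 0 and 5 passed for the mean of both doses. The class median was -1.15 (camera p = 9.17e-10, and p = 0.180 with an estimated correlation). The median was -1.505 with treated RNA in Cy5 and -0.82 with it in Cy3. YER138C, YER160C, YJR027W and YJR029W were above 0 in the Cy3 orientation (YJR027W at 0.49 against -3.12 in the other). These elements are repeated in the genome with near-identical sequence, so the 12 probes can share signal and are not 12 independent genes. The 5 that passed had drawn attention to the class. The other 7 had a median of -1.15 (camera p = 9.30e-06, and p = 0.207 with an estimated correlation). With 2 residual degrees of freedom the test with an estimated correlation has little power and does not decide, so the hypothesis stays open.

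Genes of de novo pyrimidine synthesis also appeared among the falls, and whether the class was lower was tested. Of 8 measured genes 6 were below 0 and 2 passed, URA1 (-1.19 ± 0.28), dihydroorotate dehydrogenase, and URA4 (-1.19 ± 0.19), dihydroorotase. URA1 and URA4 had drawn attention to the class, so the p of the 8 genes (camera p = 0.0403, and p = 0.338 with an estimated correlation) partly restates that. The other 6 genes had a median of -0.20 with 4 below 0. Camera did not put them below other genes (camera p = 0.422, and p = 0.557 with an estimated correlation), so a lower class is not shown. The median of the 8 was -0.54, at -1.11 with treated RNA in Cy5 and -0.11 with it in Cy3. URA2 was at -1.63 ± 1.73 and URA8 at 0.40 ± 0.48.

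The 2 frames among the largest rises lie beside other genes. YFL015C (2.19 ± 0.18) lies next to HSP12 (3.10 ± 0.88), while YOL150C (2.70 ± 0.46, measured on 6 arrays) lies next to GRE2, which was at 0.07 ± 0.10 (adjusted p = 0.683). Without the spot filter YOL150C was at 1.29.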
